A study of Sus scrofa with 35 samples.

How the data were processed

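The series holds 35 samples from pig. Of these, 18 were in the tables used here: 12 bulk RNA libraries from pig expanded potential stem cells (pEPSCs) and 6 libraries from 4-cell embryos. The pEPSC libraries form 4 groups of 3, namely wild type, OTX2 overexpression, OTX2 knockout and LEUTX overexpression. The embryo libraries form 2 groups of 3, wild type and OTX2 overexpression, and each was made from 10 pooled embryos with a Smart-seq2 type protocol, per the labels. The other 17 samples (4 ATAC-seq, 9 ChIP-seq and 4 single-cell) were not used here. Groups came from the sample titles. No label says whether the 3 libraries of a group come from separate cultures, clones or animals. The knockout column names share the prefix OTX2-KO1, which may name a single knockout line, but no label explains it.

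Each of the 4 deposited tables gives gene expression in TPM, as the authors computed it, for 6 libraries. The TPM columns were checked on the values: each sums to 997004 to 998040 after genes with a mean TPM under 1 over the 6 libraries had been left out, so each library was scaled on its own. The tables hold 13293 genes for OTX2 overexpression, 12299 for knockout, 12587 for LEUTX overexpression and 8643 for embryos. The deposited tables also hold the authors' log2 fold change and adjusted p-value for each gene, and their mean normalized count, per the file headers. The authors' up, down and stable calls are in the deposited tables as well. Per the submitters' processing notes, the tools were Trim Galore 0.6.6, STAR 2.7.3, StringTie 2.1.4, featureCounts 2.0.0, DESeq2 and others with no role given, and the genome build was Sscrofa11.1. The wild-type pEPSC values were identical in the 3 pEPSC tables, so these comparisons share their controls. Read depth per library is unknown for TPM, so no interval or detection floor was computed and a value of 0 is reported as listed at 0. In the embryo table, 10 gene names had been turned into dates and were not named here.

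Values were analysed as log2(TPM + 1), a scale that understates the fold of genes expressed at a few TPM. Genes with at least 1 TPM in at least 3 libraries were tested: 13272, 12255, 12570 and 8550 genes for the 4 tables in the order above. Each table was fitted alone with limma 3.58.1 (trended, robust empirical Bayes, statmod 1.5.0) in R 4.3.3, treated against wild type. P-values were adjusted by the Benjamini-Hochberg method and genes passed at 0.05. A second count required an absolute log2 fold change of at least 1. Every adjusted p for a gene in the text is from this limma test unless another source is named. It measures only the spread between these libraries. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.

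23 gene lists were fixed. They cover pluripotency (core, naive, formative and primed), cleavage-stage and genome activation genes, maternal oocyte transcripts, other cell types (primitive streak and mesendoderm, hypoblast and endoderm, trophoblast, neuroectoderm, fibroblast and mesenchyme, primordial germ cell, cumulus and granulosa cell), pathways (WNT targets, NODAL and TGF-beta targets, FGF-ERK targets, p53 targets, integrated and unfolded protein stress, interferon response, mitotic cell cycle, glycolysis, oxidative phosphorylation) and complexes (DNA methylation machinery, cytosolic ribosomal proteins). Some genes are in more than 1 list. Lists with at least 5 measured genes were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Members were also counted after adjustment over the list alone.

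The genes named in the text follow a rule: the targeted gene, a panel of 14 developmental regulators, the 8 highest and 8 lowest fold changes among genes that passed, had non-overlapping groups and reached a mean of 5 TPM in the higher group, and up to 4 members of each list with the smallest adjusted p. The text prints a subset of the genes this rule gives, and some of the others are withheld and not reported here. Panel genes absent from a table were not analysed there. The lists, the rule, the tests and the alternatives listed first below were set before the data were examined.

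Pairs of comparisons were set side by side by the overlap of their calls and by correlation across genes. For pairs that share the wild-type pEPSC libraries, unchanged groups were simulated 50 times against those libraries. The difference between the effects of OTX2 overexpression in embryos and in pEPSCs was tested with a limma interaction term on the genes in both tables. The tables were normalized separately, so this sets a fold change within one table against a fold change within another and compares no level across them.

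The alternatives set beforehand were no filter on low values, a pseudocount of 0.1, quantile normalization, the replicate number as a block, each library left out in turn, the 2-fold threshold, an inter-gene correlation estimated per list, and lists without the targeted gene. Median-ratio scaling of the TPM values, TPM rescaled to the nuclear genes, and a single fit over the 12 pEPSC libraries were added after seeing the data. Alternatives that need counts had also been set beforehand and were not run, because the tables hold TPM. The test for TPM values stood as set.

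The procedure was tested on simulated data with 200 genes changed by known folds. For OTX2 overexpression in pEPSCs (12226 genes) it recovered 70% of genes changed 1.5-fold and 86% of those changed 2-fold, with 7 unchanged genes called. For the knockout (12071 genes) it recovered 8% and 42%, with 3 unchanged genes called. For LEUTX overexpression (12130 genes) the shares were 82% and 96%, with 10 called, and for embryos (8364 genes) 12% and 62%, with 7 called. A planted list was found each time and no other list was called. The simulated genes varied independently of each other, so this does not test the preset inter-gene correlation on which the list calls depend.

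Ribosomal protein genes have near-identical copies in the genome, and the symbol NANOG belongs to 2 annotated loci, on chromosomes 1 and 5, so their values are uncertain. Transcript lengths were not used here, so a bias with gene length was not tested. Genes named only by a locus number were tested but not named.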

Results

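OTX2 and LEUTX are homeobox transcription factors, OTX2 of the pluripotent epiblast and forebrain and LEUTX of the embryo at genome activation. The series asks how pig cells pass between totipotent and pluripotent states. Expression was compared with wild type in pig expanded potential stem cells (pEPSCs) that overexpressed OTX2, carried an OTX2 knockout or overexpressed LEUTX, and in 4-cell embryos that overexpressed OTX2. OTX2 (gene 100512643) lies on chromosome 1 of Sscrofa11.1 at 186028575 to 186039026, and LEUTX (gene 102158775) on chromosome 6 at 48240324 to 48248568. Levels below are the authors' TPM as mean ± SD with n = 3 libraries per group, and fold changes are differences of mean log2(TPM + 1).

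In pEPSCs with OTX2 overexpression, OTX2 was at 9758, 8974 and 10819 TPM in the 3 libraries, against 258, 252 and 260 TPM in wild type. This is a log2 fold change of 5.25 (SE 0.0582, adjusted p = 1.04e-11). The pluripotency factors NANOG and SOX2 fell, NANOG (a symbol of 2 annotated loci) from 201 ± 10.2 to 32.5 ± 1.51 TPM and SOX2 from 351 ± 33.3 to 108 ± 8.86 TPM. DNMT3B, a de novo DNA methyltransferase of the early epiblast, fell from 1729 ± 105 to 285 ± 38.3 TPM (log2 fold change −2.60, SE 0.0923). POU5F1 stayed abundant and fell slightly, from 1558 ± 31.7 to 1395 ± 58.8 TPM (log2 fold change −0.16, adjusted p = 0.00267). T (brachyury), a primitive streak factor near 0 in wild type (0.0176 TPM), rose to 20.9 ± 0.833 TPM.

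Other genes rose further than OTX2. PADI3, a peptidylarginine deiminase, rose from 0.555 to 124 TPM (log2 fold change 6.32). CRABP1, which binds retinoic acid, rose from 2.86 to 273 TPM, and the transglutaminase TGM1 from 1.03 to 129 TPM. NPTX1, a neuronal pentraxin, rose to 91.8 TPM and DHRS11, a short-chain dehydrogenase, to 599 TPM. Among the lowest were TNFSF11 (log2 fold change −3.63), the chemokine CXCL13 (−3.31), AP1S2 (−3.13) and the neurotrophin BDNF (−2.88). TFAP2C was at 16.8 TPM in wild type and 16.95 TPM with OTX2 overexpression (adjusted p = 0.928). For every gene named here as risen or fallen, all 3 OTX2 libraries lay on the same side of all 3 wild-type libraries.

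Of 21 lists tested, 3 were lower than other genes. In core pluripotency, 9 of 14 measured genes fell and 2 rose, with LIN28B at a log2 fold change of −1.64 and TDGF1, a NODAL co-receptor, at −1.83 (camera adjusted p = 0.0136, and adjusted p = 0.881 with an estimated correlation). This call was not made in the fit over the 12 pEPSC libraries (adjusted p = 0.0585). In formative and primed pluripotency, 10 of 15 fell and 3 rose, among them ZIC5 (−2.66) and ETV1 (−2.17) on the falling side (adjusted p = 0.025, and adjusted p = 0.881 with an estimated correlation). This call was not made under quantile normalization (adjusted p = 0.0616). In the mitotic cell cycle, 13 of 18 fell and 3 rose, with CCNB1 and CDK1, which drive entry into mitosis, at −1.36 and −1.39 and the topoisomerase TOP2A at −0.64 (adjusted p = 0.0136, and adjusted p = 0.881 with an estimated correlation). This call too was not made under quantile normalization (adjusted p = 0.0616).

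Markers of other cell types moved both ways, and none of their lists passed as a whole. In hypoblast and endoderm, 7 of 11 genes rose and 2 fell (adjusted p = 0.297), and the endoderm factors HNF4A and GATA4 went from under 0.2 TPM to 13.4 and 9.10 TPM. In neuroectoderm, 6 of 10 rose and 2 fell (0.48). The eye-field and forebrain factors RAX (log2 fold change 2.79) and SIX3 (2.52) rose, while HESX1, another forebrain factor, fell (−1.75). Primitive streak and mesendoderm had 6 of 13 higher and 4 lower (0.964), with a median of −0.00 and a mean of 0.31. Trophoblast had 2 of 9 higher and 2 lower (0.675), fibroblast and mesenchyme 7 of 10 higher and 1 lower (0.328), and primordial germ cell 2 of 5 each way (0.964). In p53 targets, 14 of 18 rose and 4 fell (0.0777, and 0.881 with an estimated correlation), with the stress-induced genes GDF15 (4.42), SESN2 (2.41) and GADD45A (2.45) among those that rose. This list passed under median-ratio scaling (0.0334), quantile normalization (0.0468), in the fit over the 12 pEPSC libraries (0.0318) and without OTX2 overexpression library 1, 2 or 3 (0.0245, 0.0269 and 0.0303).

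The remaining lists did not pass. For naive pluripotency 4 of 9 genes rose and 3 fell (adjusted p = 0.964), and for maternal oocyte transcripts 3 of 6 rose and 1 fell (0.533). WNT targets had 6 of 8 higher and 1 lower, NODAL and TGF-beta targets 5 of 13 higher and 7 lower, and FGF-ERK targets 6 of 15 higher and 7 lower with a median of −0.06 and a mean of 0.10 (0.427 for each). Interferon response had 5 of 9 higher and 1 lower, and DNA methylation machinery 4 of 10 higher and 5 lower, with TET1, which oxidises 5-methylcytosine, at −1.88 (0.427 for each). Integrated and unfolded protein stress had 8 of 17 higher and 7 lower (0.964) and oxidative phosphorylation 9 of 18 higher and 8 lower (0.964), with NDUFA1 at 1.39. Glycolysis had 6 of 19 higher and 9 lower (0.238, and 0.881 with an estimated correlation), with lactate dehydrogenase LDHA at −1.30. It passed as lower under median-ratio scaling (0.0382, with 3 higher and 13 lower). Cytosolic ribosomal proteins had 18 of 28 higher and 6 lower (0.317), against 10 higher and 9 lower under median-ratio scaling. Fewer than 5 genes were measured for cumulus and granulosa cell (2 of 4 higher, 1 lower) and for cleavage-stage and genome activation (1 gene, which did not pass). Adjusted over the list alone, the counts were the same for every tested list but trophoblast (1 higher, 2 lower).

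Across all 13272 genes, 6485 rose and 4450 fell, and 10935 passed in all. With a 2-fold threshold, 3047 rose and 1244 fell. The median gene moved by 0.20, and median-ratio scaling gave 5593 higher and 5391 lower, while quantile normalization gave 5207 higher and 5734 lower. Past 2-fold these scalings gave 2527 higher and 1798 lower, and 1983 and 2094. The medians of the trophoblast, primordial germ cell, naive pluripotency, oxidative phosphorylation and stress lists were above 0 as deposited and turned below 0 under at least 1 of these 2 scalings. The share of TPM from mitochondrial genes was 9.02%, 9.38% and 10.1% in the OTX2 libraries and 15.7%, 15.4% and 14.5% in wild type.

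**Figure D1:**
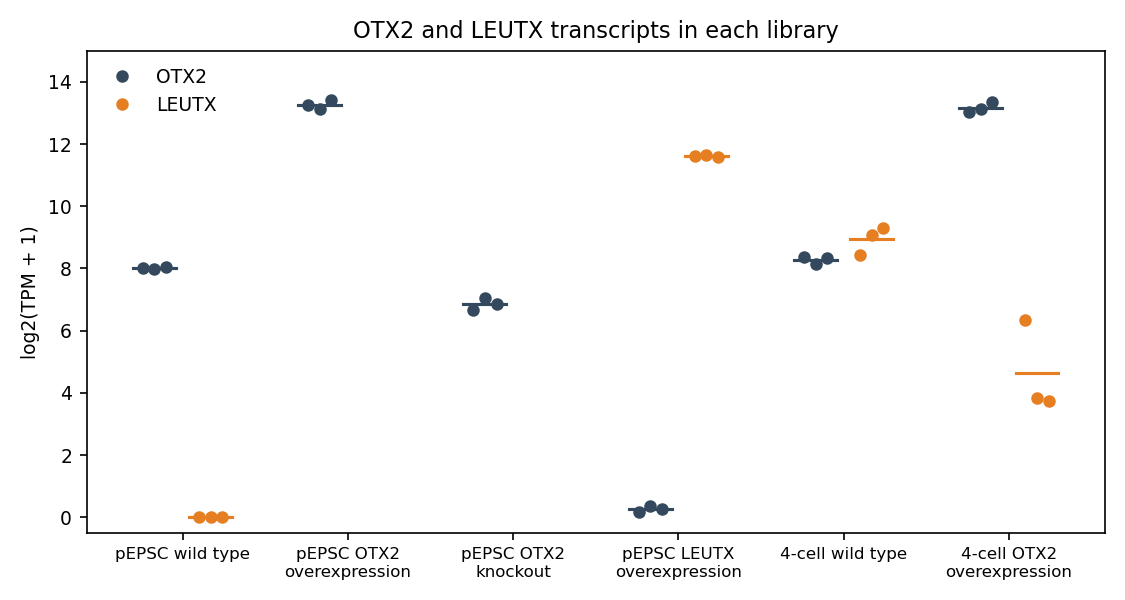
Level of OTX2 and LEUTX as log2(TPM + 1) in each library, with 1 point per library and the groups along the horizontal axis; LEUTX is shown only for the groups whose table lists it. OTX2 lies below 0.3 TPM in the 3 LEUTX overexpression libraries and at 99.5 to 130 TPM in the OTX2 knockout libraries.

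In the OTX2 knockout, OTX2 transcript was at 99.5, 130 and 114 TPM in the libraries numbered 1, 3 and 4, against 257 ± 4.26 TPM in wild type (log2 fold change −1.17, SE 0.111, adjusted p = 0.000803). The labels do not say which part of the gene was edited, so the remaining transcript says nothing on the protein. The highest fold change belonged to ANXA1, a phospholipid-binding annexin, which rose from 10.4 ± 1.86 to 707 ± 176 TPM (log2 fold change 5.94, SE 0.207). The simple-epithelium keratins KRT18 and KRT8 rose from 536 ± 19.1 to 2613 ± 228 TPM and from 1159 ± 28.8 to 4134 ± 791 TPM. TFAP2C, a factor of trophoblast and germ cells, rose from 16.8 ± 0.996 to 51.4 ± 8.32 TPM (log2 fold change 1.55, adjusted p = 0.00091). CYP26A1, which degrades retinoic acid, fell from 70.7 ± 2.68 to 2.94 ± 0.629 TPM.

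VGLL1, a TEAD cofactor, rose from 0.425 to 39.4 TPM, TDRKH, a piRNA pathway protein, from 0.821 to 37.3 TPM, and ZNF503 and CARTPT to 33.3 and 21.2 TPM. HTATIP2 fell from 43.1 to 0.749 TPM, IRS4 from 45.6 to 2.33 TPM and GABRP, a GABA receptor subunit, from 39.5 to 2.17 TPM. The forebrain factor LHX5 fell from 15.5 to 0.462 TPM. DPPA3 rose from 0.395 to 4.99 TPM and GATA6 from 0.0447 to 2.19 TPM. POU5F1 rose from 1558 ± 31.7 to 1884 ± 178 TPM (log2 fold change 0.27, adjusted p = 0.036), a call not made without any 1 of the 3 wild-type libraries or without knockout library 3 or 4 (adjusted p from 0.0984 to 0.135). SOX2, NANOG and DNMT3B did not pass (adjusted p = 0.543, 0.448 and 0.456). SOX2 was at 177, 382 and 382 TPM in the 3 knockout libraries, NANOG at 172, 257 and 265 TPM and DNMT3B at 1315, 2704 and 2469 TPM. Without library 1, NANOG (log2 fold change 0.38, adjusted p = 0.000804) and DNMT3B (0.58, adjusted p = 0.000152) passed as higher. For each gene named here as risen or fallen, all 3 knockout libraries lay on the same side of all 3 wild-type libraries.

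Knockout library 1 stood apart: 22.4% of its TPM came from mitochondrial genes, against 10.2% and 10.3% in libraries 3 and 4 and 14.5% to 15.7% in wild type. Of 20 lists tested, 5 were higher than other genes. In fibroblast and mesenchyme, 7 of 9 genes rose and none fell (8 adjusted over the list alone), with the transcription factor TWIST2 at a log2 fold change of 2.13, the collagen COL1A1 at 2.36, the actin-binding TAGLN at 1.35 and the intermediate filament VIM at 0.71 (camera adjusted p = 0.000141, and adjusted p = 0.488 with an estimated correlation). In trophoblast, 5 of 9 rose and 1 fell (7 and 1 adjusted over the list alone), EOMES being the one that fell (−1.14, adjusted p = 0.00126 for the list, and adjusted p = 0.842 with an estimated correlation). Without library 1 both lists passed (0.00123 and 0.00922), with 9 of 9 and 8 of 9 genes higher. In primordial germ cell, 4 of 5 genes rose (adjusted p = 0.0234, and adjusted p = 0.842 with an estimated correlation), including DND1 (1.34) and TDRD7 (0.77). Without any 1 knockout library, fewer than 5 of its genes were measured, so this list was not tested without library 1. At least 1 of the 5 genes thus passed the filter only through the knockout libraries and could enter only as higher. The DND1 call was not made without any 1 wild-type library or knockout library 3 or 4 (0.0571 to 0.0689), nor the TDRD7 call without any 1 wild-type library (0.0531 to 0.068).

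In p53 targets, 7 of 18 genes rose and 3 fell (9 and 3 adjusted over the list alone), with PHLDA3 at a log2 fold change of 1.54, the apoptosis effector BAX at 1.06 and the cell cycle inhibitor CDKN1A at 1.42 (adjusted p = 0.027, and adjusted p = 0.975 with an estimated correlation). In oxidative phosphorylation, 8 of 18 rose and none fell, with the complex I subunits NDUFB8 at 0.96 and NDUFA2 at 0.95 (adjusted p = 0.00998, and adjusted p = 0.488 with an estimated correlation). Under quantile normalization the oxidative phosphorylation call was not made (0.123, with 8 higher and none lower). Without library 1 neither list passed (0.079 for both). Oxidative phosphorylation had 10 of 18 higher and 3 lower with a median of 0.243, against 0.234 with all libraries. The p53 targets had 12 higher and 4 lower with a median of 0.468, against 0.379. Over all genes the median moved from −0.106 to 0.0125, so both lists came nearer to it. The mitotic cell cycle had 3 of 18 higher and 10 lower (0.0705, and 0.975 with an estimated correlation). It passed as lower under quantile normalization (0.0271) and without wild-type library 3 (0.0368).

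The other lists did not pass. Core pluripotency had 5 of 15 genes higher and none lower (0.199), with UTF1 at 2.48, and naive pluripotency 4 of 9 higher and 1 lower (0.152), with DPPA5 at 2.31. Formative and primed pluripotency had 1 of 14 higher and 5 lower (0.601), with POU3F1 at −2.56 and the cadherin CDH2 at −2.60, a median of 0.04 and a mean of −0.46. Primitive streak and mesendoderm had 3 of 11 higher and 5 lower (0.919), hypoblast and endoderm 1 of 9 each way (0.919) and neuroectoderm 2 of 6 higher and 3 lower (0.66). WNT targets had 1 of 7 higher and 2 lower (0.919), NODAL and TGF-beta targets 3 of 12 each way (0.919) and FGF-ERK targets 4 of 16 higher and 1 lower (0.314). Integrated and unfolded protein stress had 3 of 16 higher and 4 lower (0.919), interferon response 2 of 8 higher and 1 lower (0.601) and DNA methylation machinery 1 of 10 higher and 4 lower (0.395). Glycolysis had 2 of 19 higher and 3 lower (0.919), and cytosolic ribosomal proteins 7 of 28 higher and 4 lower (0.314), against 6 higher and none lower under median-ratio scaling. Adjusted over the list alone, the stress list had 5 each way, DNA methylation 1 and 5, glycolysis 2 and 2, ribosomal proteins 8 and 4, and the other lists in this paragraph the same counts. Below 5 measured genes were maternal oocyte transcripts (2 of 4 higher), cumulus and granulosa cell (1 of 3 higher) and cleavage-stage and genome activation (1 gene, which did not pass).

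Across 12255 genes, 1820 rose and 2732 fell (4552 in all), and with a 2-fold threshold 500 rose and 734 fell. Without knockout library 1, 3894 rose and 3812 fell (7706). Without wild-type library 1, 2 or 3 the count was 2055, 2280 and 2421. The median gene moved by −0.11. Median-ratio scaling gave 2965 higher and 2891 lower and quantile normalization 2984 and 3048. Past 2-fold more genes rose than fell under these scalings (658 and 560, 664 and 523) and without knockout library 1 (626 and 502). Under the scalings the medians of the hypoblast, glycolysis and ribosomal protein lists changed sign in at least 1.

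In the LEUTX overexpression libraries LEUTX was at 3171, 3187 and 3073 TPM, and it was listed at 0 in all 3 wild-type libraries. OTX2 fell from 257 ± 4.26 TPM to 0.131, 0.294 and 0.209 TPM, a log2 fold change of −7.74 (SE 0.0742, adjusted p = 1.48e-11). WNT8A, a ligand of the primitive streak, rose from 4.61 ± 0.917 to 263 ± 16.7 TPM (log2 fold change 5.56, SE 0.108). TFAP2C rose from 16.8 ± 0.996 to 102 ± 6.48 TPM, and LEFTY2, a NODAL antagonist, from 674 ± 48.8 to 4122 ± 66.7 TPM. DNMT3B fell from 1729 ± 105 to 366 ± 27.4 TPM, as it did with OTX2 overexpression.

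FXYD4, an ion transport regulator listed at 0 in wild type, was at 34.9, 40.9 and 38.9 TPM, while RESP18 rose to 78.3 TPM and UGT1A6, a glucuronosyltransferase, to 102 TPM. CYP26A1 fell from 70.7 TPM to 0.0240 TPM in library 1 and was listed at 0 in libraries 2 and 3. IGFBP2 fell from 260 to 4.04 TPM, the WNT receptor FZD7 from 105 to 2.32 TPM and SOX21 from 35.1 to 0.133 TPM. SOX2 fell from 351 ± 33.3 to 264 ± 12.6 TPM and NANOG from 201 ± 10.2 to 153 ± 5.92 TPM, while DPPA3 rose from 0.395 to 2.39 TPM. The SOX2 call was not made in the fit over the 12 pEPSC libraries (log2 fold change −0.41, adjusted p = 0.165). POU5F1 rose from 1558 ± 31.7 to 1676 ± 26.7 TPM (log2 fold change 0.11, adjusted p = 0.00655), which is the shift of the median gene (0.11), and under median-ratio scaling its log2 fold change was −0.0036 (adjusted p = 0.953). In the fit over the 12 libraries the POU5F1 call was not made either (adjusted p = 0.179). For every gene named here as risen or fallen, all 3 LEUTX libraries lay on the same side of all 3 wild-type libraries.

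Of 21 lists tested, 3 were lower than other genes. In glycolysis, 15 of 19 genes fell and 2 rose, among them the enzymes PGAM1 (925 to 479 TPM), TPI1 (627 to 355 TPM) and LDHA (249 to 128 TPM) and the lactate exporter SLC16A3 (19.3 to 1.82 TPM). Its camera adjusted p was 2.3e-05 (adjusted p = 0.359 with an estimated correlation). In hypoblast and endoderm, 7 of 8 fell and 1 rose (adjusted p = 0.00593, and adjusted p = 0.359 with an estimated correlation). FOXA2, an endoderm factor at 20.2 TPM in wild type, was listed at 0 in all 3 LEUTX libraries, and the basement membrane collagen COL4A1 fell from 41.2 to 8.28 TPM. In fibroblast and mesenchyme, 7 of 9 fell and 2 rose, with TAGLN (−2.88) and VIM (−1.77) lower and fibronectin FN1 (0.47) higher (adjusted p = 0.0312 for the list, and adjusted p = 0.359 with an estimated correlation). The FN1 call was not made in the fit over the 12 pEPSC libraries (0.154). The call of the list was not made under quantile normalization (0.0948), under median-ratio scaling (0.104) or without wild-type library 1, 2 or 3 (0.156, 0.154 and 0.146).

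Primitive streak and mesendoderm had 5 of 10 genes higher and 5 lower (adjusted p = 0.969): NODAL rose with WNT8A and LEFTY2 (log2 fold change 1.59), while EOMES (−3.65) and the NODAL and WNT antagonist CER1 (−4.14) fell. In NODAL and TGF-beta targets 6 of 12 rose and 4 fell (0.459), LEFTY2 and NODAL among those that rose. Core pluripotency had 5 of 14 higher and 8 lower (0.0975), with LIN28A at −1.56 and TDGF1 at 1.58, and GDF3, at 3.70 TPM in wild type, listed at 0 in the 3 LEUTX libraries. Neuroectoderm had 1 of 5 higher and 4 lower (0.0975), including HESX1 (−3.40) and LHX5 (−3.47). Primordial germ cell had 5 of 5 higher (0.0905), trophoblast 2 of 7 higher and 5 lower (0.0838), naive pluripotency 5 of 9 higher and 3 lower (0.757), and formative and primed pluripotency 4 of 13 higher and 8 lower (0.0975). Trophoblast passed as lower in the fit over the 12 pEPSC libraries (0.0323), while in the separate fit its adjusted p was 0.359 with an estimated correlation.

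The remaining lists did not pass: maternal oocyte transcripts (4 of 5 higher, adjusted p = 0.173), WNT targets (5 of 8 higher, 1 lower, 0.445), FGF-ERK targets (4 of 15 higher, 9 lower, 0.0905), p53 targets (10 of 18 higher, 4 lower, 0.501) and integrated and unfolded protein stress (5 of 17 higher, 6 lower, 0.951). The same held for interferon response (3 of 8 each way, 0.969), DNA methylation machinery (2 of 10 higher, 4 lower, 0.173), mitotic cell cycle (6 of 18 higher, 9 lower, 0.173, median −0.10 and mean 0.01), oxidative phosphorylation (11 of 18 higher, 5 lower, 0.512) and cytosolic ribosomal proteins (7 of 28 higher, 14 lower, 0.0975). Adjusted over the list alone, maternal transcripts had 5 higher, NODAL and TGF-beta targets 7 and 4, p53 targets 10 and 5 and interferon response 4 and 3, and the counts of the other tested lists were the same. Of fewer than 5 measured genes, 2 of 2 rose in cumulus and granulosa cell and 2 of 2 in cleavage-stage and genome activation, LEUTX itself included. In all, 5233 of 12570 genes rose and 3528 fell (8761), with 1232 and 465 past 2-fold. Median-ratio scaling gave 4467 higher and 4495 lower and quantile normalization 4183 and 4740, with 1042 and 554, and 855 and 691, past 2-fold. The medians of the stress and interferon lists changed sign under 1 of them. The mitochondrial share was 15.9% to 16.1%, near that of wild type.

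**Figure D2:**
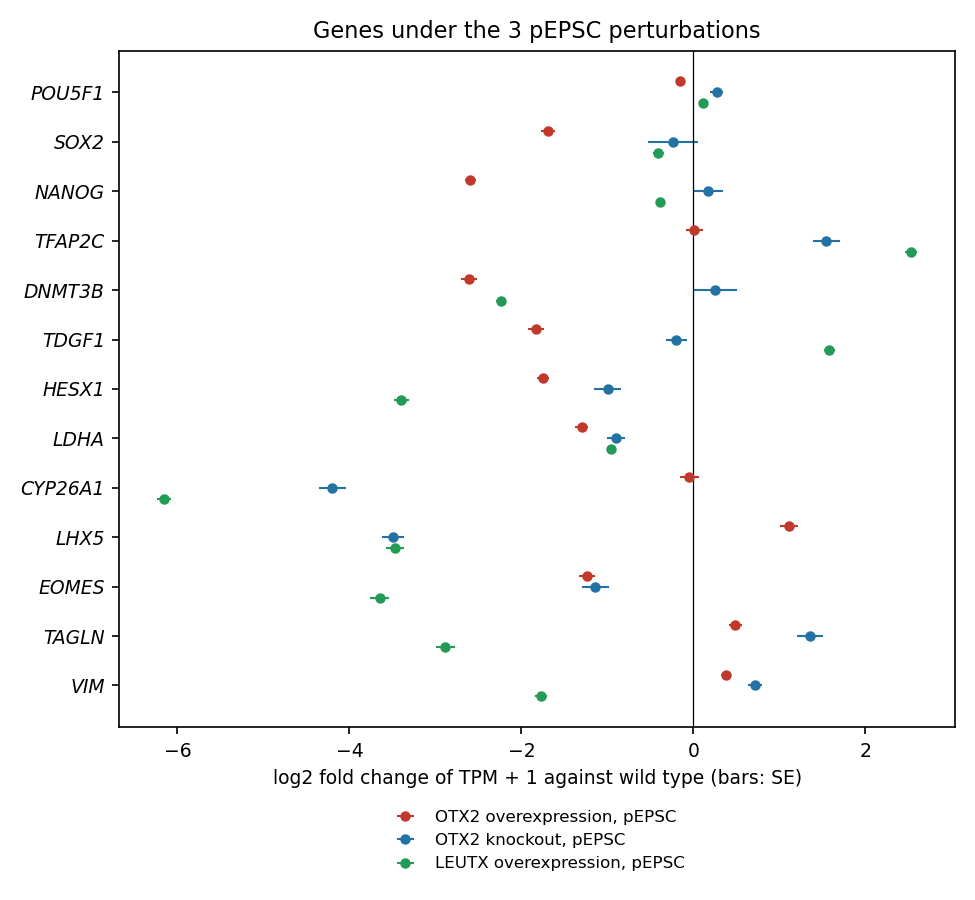
Log2 fold change against wild type (bars on the points are standard errors from limma, n = 3 against 3 libraries) of 13 genes in the 3 pEPSC comparisons, OTX2 overexpression, OTX2 knockout and LEUTX overexpression. DNMT3B lies at −2.60 with OTX2 overexpression and −2.24 with LEUTX overexpression, and TFAP2C at 1.55 in the knockout and 2.53 with LEUTX overexpression.

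OTX2 overexpression and OTX2 knockout moved more genes the same way than opposite ways. The knockout libraries keep OTX2 transcript, and no value shows loss of the protein. Of 12109 genes tested in both, 1203 rose in both and 1789 fell in both (2992), while 810 went opposite ways, 21.3% of the genes called in both. NANOG, SOX2 and DNMT3B, which fell with OTX2 overexpression, were not called in the knockout, whereas EOMES (log2 fold change −1.23 and −1.14) and LDHA (−1.30 and −0.90) fell in both. Without knockout library 1, NANOG (log2 fold change 0.38) and DNMT3B (0.58) passed as higher, opposite to overexpression. LHX5 rose with OTX2 overexpression (1.11) and fell in the knockout (−3.50). Independent lists of these sizes would share 1773 genes the same way and 1853 opposite. The fold changes correlated across genes (Pearson r = 0.378, Spearman rho = 0.434), with a covariance of 0.237, where genes are not independent replicates. Unchanged groups simulated against the same wild-type libraries gave r = 0.503, a covariance of 0.0197 and no shared calls. Groups that share controls correlate by construction, so this r is no benchmark for the observed r. Few calls are made in unchanged groups, so few could be shared. Part of the excess over independent lists may come from the shared wild-type libraries. Past 2-fold in both, 416 genes went the same way and 93 opposite ways. Without knockout library 1 the counts were 5086 the same way and 1378 opposite, and without wild-type library 1, 2 or 3 they were 1348 and 312, 1530 and 367, and 1651 and 361. With any 1 library left out, the opposite share of the genes called in both was 17.9% to 22.8%.

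OTX2 and LEUTX overexpression changed 5255 of 12369 genes the same way (3178 higher and 2077 lower in both), and 1939 genes went opposite ways. DNMT3B (log2 fold change −2.60 and −2.24), LIN28B (−1.64 and −0.66) and LDHA (−1.30 and −0.96) fell in both. Independent lists would share 3583 and oppose 3432. Across genes, r was 0.380 and rho 0.414 with a covariance of 0.279, against a simulated r of 0.503 and covariance of 0.00625 with no shared calls. Past 2-fold, 740 were shared and 110 opposite. OTX2 knockout and LEUTX overexpression, a pair added after seeing the data, shared the rise of TFAP2C and DPPA3 and the fall of CYP26A1, LHX5 and EOMES. Here 1824 of 12016 genes changed the same way and 1399 opposite ways, where independent lists would give 1467 and 1576. Without knockout library 1 the counts were 3120 and 2267, and without wild-type library 1, 2 or 3 they were 793 and 530, 925 and 627, and 1029 and 656. The opposite share was 43.4%, and 38.9% to 44.1% with any 1 library left out. Across genes r was 0.117 and the covariance 0.0539, against a simulated r of 0.503 and covariance of 0.0191. In both pairs, part of the excess over independent lists or in covariance may again come from the shared controls. The simulated r is no benchmark for the observed r in these pairs either.

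**Figure D3:**
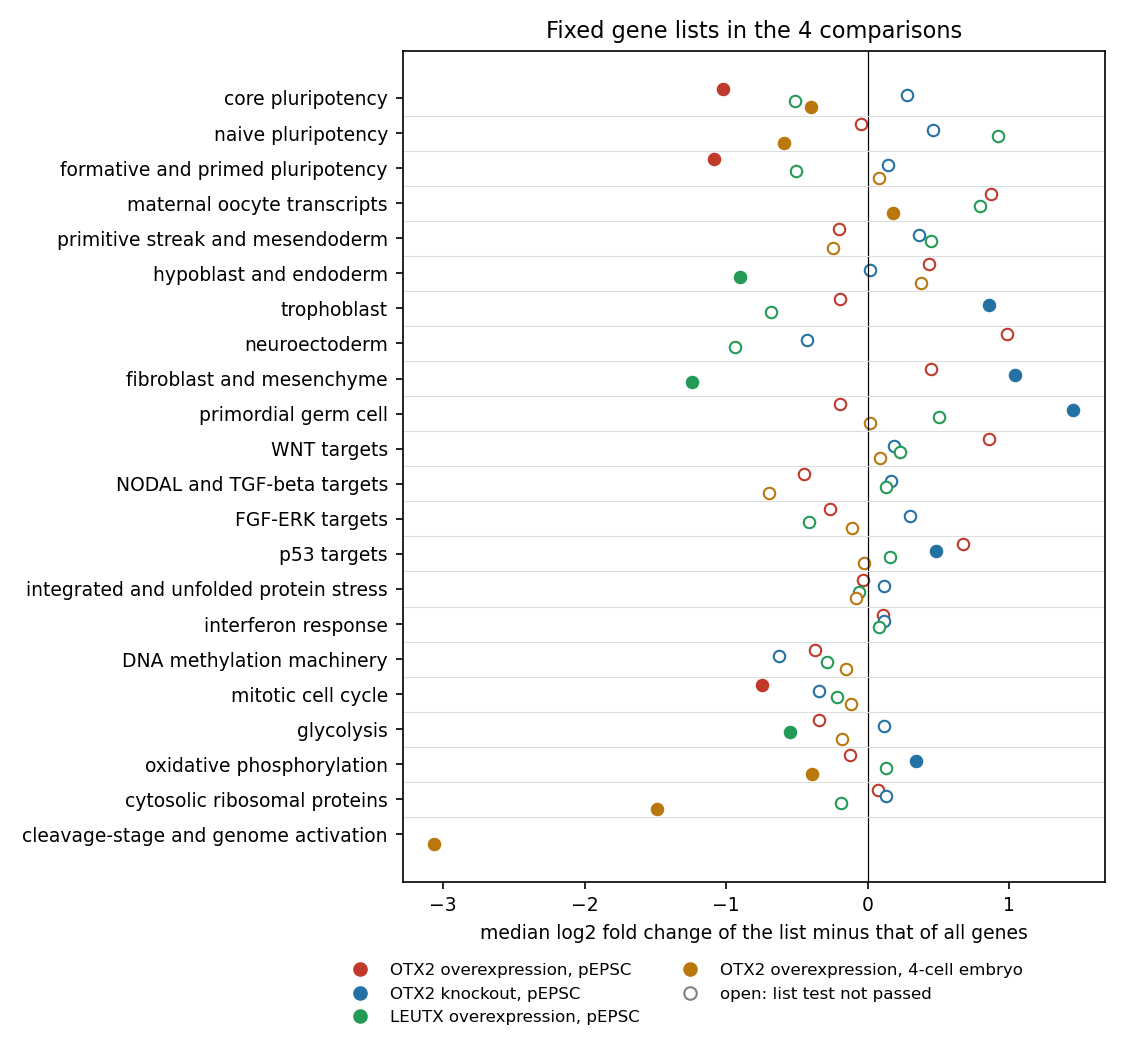
Median log2 fold change of each gene list minus that of all tested genes, for the 4 comparisons, with filled points for lists that passed the camera test at the preset correlation. In 4-cell embryos the cleavage-stage and genome activation list (−3.06) and the cytosolic ribosomal protein list (−1.49) lie lowest.

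In 4-cell embryos with OTX2 overexpression, OTX2 was at 8276, 9001 and 10565 TPM, against 327, 283 and 321 TPM in wild-type embryos (log2 fold change 4.89, SE 0.136, adjusted p = 1.35e-06). LEUTX fell from 346, 538 and 631 TPM to 80.8, 13.3 and 12.4 TPM (log2 fold change −4.29, SE 0.626, adjusted p = 0.00323). TFAP2C fell from 267 ± 107 to 25.5 ± 5.96 TPM and KLF17, a factor of the cleavage-stage embryo, from 13.3 ± 7.97 to 1.07 ± 1.06 TPM. NANOG fell from 28.7 ± 13.5 to 1.43 ± 2.39 TPM, with 1 OTX2 library listed at 0. POU5F1 was at 33.2 ± 0.779 and 37.0 ± 6.68 TPM (adjusted p = 0.507).

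Genes outside the panel fell as well. ANG, a ribonuclease, fell from 83.2 to 1.37 TPM (log2 fold change −5.05, adjusted p = 8.12e-05), EMG1, a ribosome biogenesis factor, from 46.9 to 1.35 TPM, TFAM, the mitochondrial transcription factor, from 114 to 8.11 TPM and the actin-binding TMSB10 from 1277 to 107 TPM. Among genes that rose were the HLH regulator ID3 from 216 to 789 TPM, RGS2 from 70.6 to 212 TPM and CDK5R1 from 3.73 to 16.9 TPM. CDK5R1 was at 10.3, 0.46 and 0.427 TPM in wild type, and its call (adjusted p = 0.0263) was not made under median-ratio scaling (0.0592), with TPM rescaled to nuclear genes (0.0509) or without wild-type library 2 or 3 or OTX2 library 2 or 3 (0.0718 to 0.0947). DPPA3 rose from 1158 ± 148 to 1776 ± 78.5 TPM (adjusted p = 0.0122), a call not made under quantile normalization (0.0569), under median-ratio scaling (0.142) or without wild-type library 2 (0.0543) or OTX2 library 2 (0.052). DNMT3B was at 4.42 and 6.59 TPM (adjusted p = 0.073, and 0.0314 without OTX2 library 1). For every gene named here as risen or fallen, all 3 OTX2 libraries lay on the same side of all 3 wild-type libraries.

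**Figure D4:**
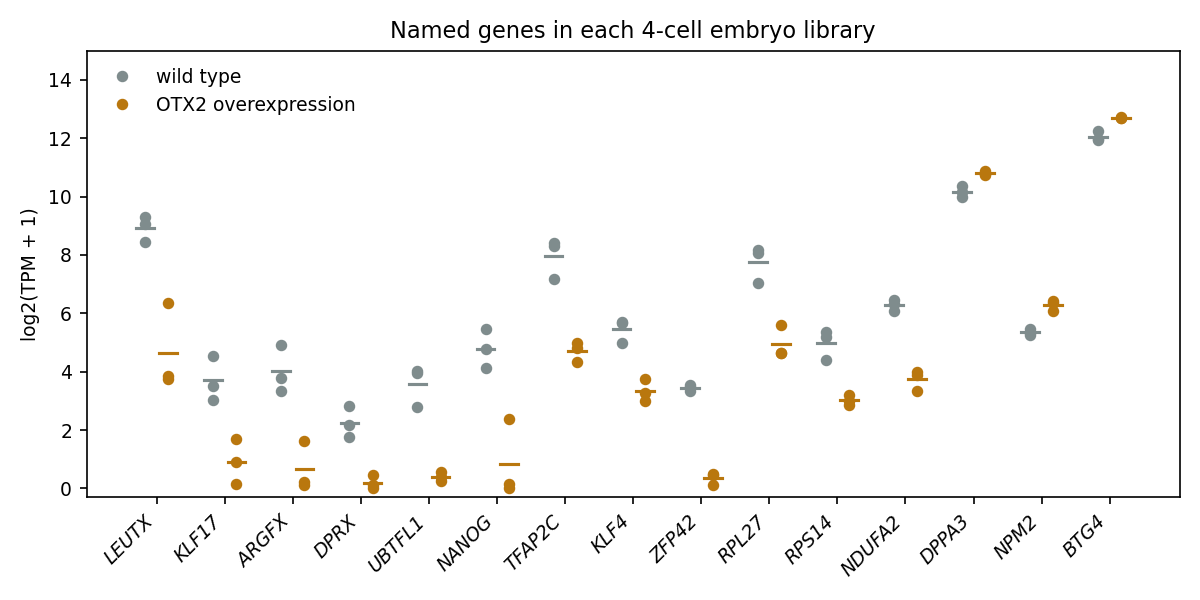
Level in log2(TPM + 1) of 15 genes in each 4-cell embryo library, wild type and OTX2 overexpression, with 1 point per library (n = 3 per group). LEUTX lies at 346 to 631 TPM in wild type and at 12.4 to 80.8 TPM with OTX2 overexpression.

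Of 18 lists tested, 6 passed. In cleavage-stage and genome activation, 6 of 7 genes fell and none rose, with the PRD-like homeobox genes ARGFX (log2 fold change −3.36) and DPRX (−2.05) and with UBTFL1 (−3.19) beside LEUTX (camera adjusted p = 7.55e-08, and adjusted p = 0.205 with an estimated correlation). Without any 1 wild-type library, fewer than 5 of these genes were measured and the list was not tested. Some of these genes thus passed the filter only through the wild-type libraries and could enter only as lower. In cytosolic ribosomal proteins, whose near-identical gene copies make single values uncertain, 17 of 28 fell and none rose, including RPL27 from 228 to 31.7 TPM, RPL23 from 14.4 to 1.98 TPM and RPS14 from 31.8 to 7.12 TPM (adjusted p = 3.71e-13, and adjusted p = 0.205 with an estimated correlation). In naive pluripotency, 5 of 10 fell and 1 rose, with ZFP42 at −3.09 and KLF4 at −2.11 (adjusted p = 0.00098, and adjusted p = 0.205 with an estimated correlation). In core pluripotency, 3 of 10 fell and none rose: NANOG, GDF3 (−2.42) and DPPA2 (−1.18). Its adjusted p was 0.0134 (adjusted p = 0.373 with an estimated correlation), and 0.207 and 0.0718 without wild-type library 2 and 3. The DPPA2 call (adjusted p = 0.0354) was not made with the replicate number as a block (0.0646) or without wild-type library 2 or 3 or OTX2 library 2 or 3 (0.0912 to 0.122).

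In oxidative phosphorylation, 5 of 17 genes fell and 1 rose, with NDUFA2 at a log2 fold change of −2.53 and COX5B at −0.79 against UQCRB at 1.24 (adjusted p = 0.00122, and adjusted p = 0.205 with an estimated correlation). In maternal oocyte transcripts, 8 of 22 rose and none fell (9 adjusted over the list alone), with the oocyte chromatin factor NPM2 at 0.94, KHDC3L of the subcortical maternal complex at 1.10, the translation regulator CPEB1 at 1.14 and BTG4, which acts in maternal mRNA decay, from 4279 to 6701 TPM. Its adjusted p was 0.0447 (adjusted p = 0.557 with an estimated correlation), and 0.0849, 0.0718 and 0.145 without wild-type library 1, wild-type library 3 and OTX2 library 3. Under median-ratio scaling 3 of the 22 rose, and BTG4 was not called (adjusted p = 0.0841), nor under quantile normalization (0.0844). Mitochondrial genes made up 51.4% to 51.9% of TPM in the OTX2 libraries and 55.7% to 57.7% in wild type.

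The other lists did not pass. Formative and primed pluripotency had 2 of 8 genes higher (adjusted p = 0.234) and hypoblast and endoderm 2 of 5 higher (0.234). Primitive streak and mesendoderm had 2 of 5 lower (0.115, median 0.03 and mean −0.66), with GSC from 7.71 to 0.383 TPM. Primordial germ cell had 4 of 10 higher and 1 lower (0.839), WNT targets 1 of 5 each way (0.962), NODAL and TGF-beta targets 1 of 7 higher and 3 lower (0.194) and FGF-ERK targets 3 of 10 higher and 2 lower (0.525, median 0.17 and mean −0.11). p53 targets had 2 of 10 each way (0.933), integrated and unfolded protein stress 3 of 11 higher and 1 lower (0.933), and mitotic cell cycle 3 of 17 higher (0.962). DNA methylation machinery had 2 of 10 lower (0.306, median 0.13 and mean −0.28), with TDG, which excises oxidised methylcytosine, from 16.99 to 0.665 TPM, and glycolysis 1 of 12 each way (0.284). Adjusted over the list alone, the counts were 1 and 2 for primitive streak, 4 higher for hypoblast, 2 and 3 for NODAL, 1 higher for the mitotic list and otherwise the same. Under median-ratio scaling no gene of the formative, hypoblast, germ cell, WNT, FGF-ERK, stress and mitotic lists was called higher. Fewer than 5 genes were measured for trophoblast (1 of 2 lower), neuroectoderm (1 of 4 each way), interferon response (1 of 3 higher), fibroblast and mesenchyme (3 genes, none passing) and cumulus and granulosa cell (1 gene, which did not pass).

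In embryos 1835 of 8550 genes rose and 678 fell (2513), but past 2-fold 162 rose and 468 fell. The median gene moved by 0.28, and median-ratio scaling gave 292 higher and 846 lower (1138), quantile normalization 611 and 755 (1366) and TPM rescaled to nuclear genes 656 and 739 (1395). Under median-ratio scaling the medians of the primitive streak, FGF-ERK, p53, stress, DNA methylation, mitotic and glycolysis lists turned below 0. The count was 849 and 1255 without wild-type library 2 and 3, and 871 and 1367 without OTX2 library 2 and 3. The rises past 2-fold varied more than the falls: 25 rose and 580 fell under median-ratio scaling, 59 and 524 under quantile normalization and 318 and 531 with a pseudocount of 0.1. They were 253 and 425, 108 and 303, and 157 and 302 without wild-type library 1, 2 and 3, and 375 and 481, 108 and 399, and 101 and 432 without OTX2 library 1, 2 and 3.

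OTX2 overexpression changed few genes the same way in embryos and in pEPSCs. Of 7406 genes tested in both, 487 rose in both and 258 fell in both (745), while 1054 went opposite ways, where independent lists would give 830 and 969. These comparisons share no control libraries, and across genes r was 0.00907 and rho 0.0321. NANOG, ZFP42, KLF4 and GDF3 fell in both. LDHA fell in pEPSCs (log2 fold change −1.30) and rose in embryos (1.20). Past 2-fold, 65 genes went the same way and 61 opposite ways, where independent lists would give 68.2 and 63.3. Under median-ratio scaling the counts were 451 and 393, where independent lists would give 486 and 346. The same-way count thus stayed below that of independent lists in both settings. The counts were 233 the same way and 369 opposite, and 374 and 526, without wild-type embryo library 2 and 3, and 258 and 367, and 359 and 629, without embryo OTX2 library 2 and 3. Without embryo OTX2 library 1, 988 went the same way and 1032 opposite, where independent lists would give 925 and 1096, with rho at 0.114. The same-way count thus lay above that of independent lists there and below it with all libraries.

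In the authors' deposited table, 2752 genes were up and 2227 down with OTX2 overexpression in pEPSCs, 863 and 780 in the knockout, 1339 and 747 with LEUTX overexpression, and 933 and 1439 in embryos. The deposited calls start at an absolute log2 fold change of 1.0 in the pEPSC tables and of 0.311 in the embryo table, so the embryo counts follow another threshold. Across genes, their log2 fold changes correlated with those computed here at r = 0.926, 0.944, 0.945 and 0.933, and genes are not independent replicates. Of the genes past 2-fold here that the deposited table calls, the 2 sources gave the same direction for 2571 up and 1230 down, 486 and 617, 1089 and 456, and 134 and 463 genes, and opposite directions for 3, 1, 0 and 0. With no fold threshold on the genes that passed here, the embryo agreement was 722 up and 659 down, with 0 opposite. The 2 groups of 3 libraries did not overlap for 83.3%, 55.7%, 73.5% and 49.1% of genes, against 10% by chance.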

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

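The tests of mitochondrial scaling, of a single library, of a mislabelled sample and of the loss of OTX2 as driver were chosen after their results were seen, whereas those of shared noise, of wild type standing apart, of slower exchange and of the splits were set before.

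The effect of OTX2 overexpression differed between embryos and pEPSCs for 4920 of 7478 genes in both tables, by the limma interaction term on tables that were normalized separately. Of 40 genes of the text measured in both, 34 differed. Of these 21 had opposite signs, 9 with a change called in both systems and 12 without a call in at least 1. The naming rule takes large or clearly called changes in either comparison, which favours genes that differ. The share among named genes is therefore no separate result. Values here are the log2 fold change in embryos minus that in pEPSCs. Genes that were lower in embryos relative to their change in pEPSCs were CRABP1 (−6.79), ANG (−6.13), TMSB10 (−4.67), GSC (−4.14), EMG1 (−3.98), GADD45A (−3.34), TFAP2C (−3.28), TFAM (−2.68), GATA4 (−2.56), TDG (−2.35), ZFP42 (−1.61) and KLF4 (−1.19). Of oxidative phosphorylation and ribosomal protein genes, NDUFA2 (−3.66), RPS14 (−2.73), RPL27 (−2.55), RPL23 (−2.25), NDUFA1 (−1.50) and COX5B (−1.38) were on that side and UQCRB (1.48) on the other. The other genes were higher in embryos relative to pEPSCs: CXCL13 (3.58), DNMT3B (3.08), AP1S2 (2.99), ZIC5 (2.95), LDHA (2.50), BDNF (2.44), CDK5R1 (2.42), ETV1 (2.34), LIN28B (2.20), HESX1 (2.11), CDK1 (1.72), ID3 (1.61), CCNB1 (1.52), TET1 (1.35) and NPM2 (1.00).

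OTX2 overexpression and OTX2 knockout in pEPSCs changed many genes the same way, EOMES and LDHA among the falling ones. Noise shared through the wild-type libraries would lower the covariance of the fold changes when each comparison takes different wild-type libraries, but it was 0.205 or more in 6 such arrangements against 0.237 with shared ones. Rescaling TPM to the nuclear genes left 21.4% of genes called in both opposite, which argues against the mitochondrial share as the cause. If wild type stood apart from every engineered line, over 80% of these genes were expected to move that way under LEUTX too, and under 70% if not. The share was 63.8% of 2935 (64.2% to 65.1% without 1 wild-type library), under the lower bound, and 23.9% were called the other way. LEUTX overexpression may move these genes by effects of its own and so lower the share. The test therefore cannot decide whether wild type standing apart accounts for these genes. It stays open, as a hypothesis, that pEPSCs may respond alike to either departure from wild-type OTX2, or that clones and culture differ between lines, which no label describes. The knockout libraries keep OTX2 transcript at 99.5 to 130 TPM and no value shows loss of the protein. The knockout may therefore not stand for loss of OTX2.

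Genome activation and ribosomal protein genes were lower in embryos with OTX2 overexpression: of 35 members of both lists, 23 fell, LEUTX and RPL27 among them, with a median log2 fold change of −1.46. With TPM rescaled to the nuclear genes the median was −1.65. Mitochondrial genes took a smaller share of TPM in the OTX2 libraries, which raises nuclear TPM there, so rescaling could only deepen the fall. That share therefore cannot produce it. With each library left out the median was −1.20 or lower, so no single library accounts for the fall of the 2 lists pooled. Of the 35 members, 28 are ribosomal proteins, and the genome activation list alone was not tested without any 1 wild-type library. Some genes of that list passed the filter only through the wild-type libraries and could enter only as lower. A slower exchange of maternal for embryonic transcripts could produce the pattern: the 737 genes highest in pEPSCs over embryos had a median differing by −0.16 from that of the 737 lowest, which lies between the bounds set for it (−0.2) and against it (−0.1). Of the highest 88 rose and 106 fell, and of the lowest 217 rose and 47 fell. The ranking left out only mitochondrial genes, so genes of the 2 lists stayed in it. RPL23, for example, was at 2981 TPM in wild-type pEPSCs and 14.4 TPM in wild-type embryos. The fall of such genes is the pattern itself and can lower the median of the highest genes, toward slower exchange. The ranking and the fold changes share the wild-type embryo libraries, and noise in those libraries shifts this difference upward, against slower exchange. The difference was past the bound for it without wild-type library 1 or OTX2 library 3 (−0.24 and −0.23), and past the bound against it without wild-type library 3 or OTX2 library 1 (−0.09 and −0.06), so it decides neither way. A direct effect of OTX2 on these genes and a delay of the embryos thus cannot be told apart here, since each treatment was sampled at the 4-cell stage only. These need not be the only causes. The embryo controls are labelled wild type only, so indirect or other effects of the treatment cannot be separated either.

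OTX2 transcript fell below 0.3 TPM in every library with LEUTX overexpression. A mislabelled sample is argued against by LEUTX itself, at 3073 TPM in the lowest of these libraries. If loss of OTX2 drove the other changes, genes past 2-fold in both knockout and LEUTX overexpression would go the same way, and 56.8% of 310 did. The knockout libraries keep OTX2 transcript at 99.5 to 130 TPM and no value shows loss of the protein, so this leaves open whether loss of OTX2 drives the other changes. Repression of OTX2 by LEUTX, direct or not, may be a biological explanation and stays a hypothesis.

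With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: only 1 split, the real one, reached each count. The real counts were 10935 genes for OTX2 overexpression in pEPSCs, 4552 for the knockout, 8761 for LEUTX overexpression and 2513 in embryos, and the highest of the other splits was 0 in each.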

How the results depend on the processing

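Median-ratio scaling, TPM rescaled to nuclear genes and the fit over the 12 pEPSC libraries were chosen after seeing the data, and the other alternatives before. The counts of genes changed at any fold stayed within 1.5 times with no filter on low values and with a pseudocount of 0.1, but the embryo genes higher past 2-fold went from 162 to 318 with that pseudocount. The 2-fold threshold, stricter by construction, left 4291, 1234, 1697 and 630 genes for OTX2 overexpression, knockout, LEUTX overexpression and embryos. For the pairs it left 93 genes opposite between OTX2 overexpression and knockout, 740 shared by OTX2 and LEUTX overexpression and 65 shared by OTX2 overexpression in pEPSCs and embryos. An inter-gene correlation estimated per list left 0 lists in each of the 4 comparisons, against 3, 5, 3 and 6, with lowest adjusted p of 0.881, 0.488, 0.359 and 0.205.

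In embryos the count of 2513 became 1366 under quantile normalization, 1138 under median-ratio scaling and 1395 with nuclear TPM, and the genes shared with pEPSCs became 451 under median-ratio scaling. The lists passing with OTX2 overexpression in pEPSCs became 5 under median-ratio scaling. Among the named genes that passed, only POU5F1 under LEUTX overexpression changed sign, at −0.0036 with median-ratio scaling. With 1 library left out, the counts ranged from 2055 to 7706 for the knockout and from 849 to 2844 in embryos, and lists passing from 2 to 6 and from 3 to 6. Opposite changes between OTX2 overexpression and knockout ranged from 312 to 1378, and changes shared by pEPSCs and embryos from 233 to 988. Where a result moved, the cause was not tested. Of the named genes that passed, the most that lost their call under 1 setting, or over the libraries left out in turn, was 3 in each of knockout, LEUTX overexpression and embryos, and 0 with OTX2 overexpression in pEPSCs.

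The replicate number as a block left 10634 genes for OTX2 overexpression in pEPSCs, 8163 for LEUTX overexpression and 1619 in embryos. Libraries with the same number did not deviate together: correlations were −0.07, −0.10 and −0.16 for OTX2 overexpression, 0.04, −0.11 and −0.18 for LEUTX and −0.21, −0.17 and 0.07 in embryos, and not every library correlated best with its own number. No paired analysis was possible for the knockout because its columns are numbered 1, 3 and 4 and its titles 1, 2 and 3. Size factors, the DESeq2 test and a joint fit on counts were planned for counts and not run. The authors' mean normalized counts sum to 16199233, 15356997, 17715902 and 19272358 over the genes of the 4 tables in the order above, an average on their normalized scale. The depth of each library is not given, so no limit per library was computed.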

Other observations

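The tests of gene families in this part were chosen after the results were seen.

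Families of genes that share a symbol stem and hold at least 20 tested members were compared with all other genes (one-sided Fisher's exact test, Benjamini-Hochberg over 410 families and directions; genes are not independent). With OTX2 overexpression in pEPSCs, 21 of 28 genes for the small subunit of the mitochondrial ribosome (MRPS) fell (adjusted p = 0.00121), with a median log2 fold change of −0.30 and −0.49 under median-ratio scaling. Those for the large subunit (MRPL) did not pass, with 23 of 47 lower (0.279) and a median of −0.16. Genes named EIF, mostly translation initiation factors, fell in 31 of 48 (0.0013), centrosomal proteins (CEP) in 23 of 36 (0.0125), nucleoporins (NUP) in 15 of 21 (0.0202) and METTL genes in 15 of 22 (0.0318). Collagens (COL) rose in 24 of 31 (0.0306), with a median of 1.06 and 0.87 under median-ratio scaling, and LRRC genes in 27 of 36 (0.0318). EIF (30 of 48, 0.000146), MRPS (17 of 28, 0.0163) and NUP genes (13 of 21, 0.0378) were also lower with LEUTX overexpression. There DDX genes passed as lower too (18 of 33, 0.0378, against 0.168 for 18 of 33 with OTX2 overexpression) and TMEM genes as higher (102 of 183, 0.00312), while MRPL did not pass (21 of 47 lower, 0.173).

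In the OTX2 knockout, CEP genes fell in 18 of 35 (51.4%, against 22.3% of other genes, adjusted p = 0.0094) and zinc finger genes (ZNF) in 74 of 228 (0.0125), with medians of −0.55 and −0.34, and −0.47 and −0.26 under median-ratio scaling. The stem RPS passed as higher there (14 of 42, 0.0464, median 0.04), but 10 of its 42 genes and 3 of the 14 are S6 kinases. None of the 28 MRPS genes fell there and 7 rose, and of 47 MRPL genes 1 fell and 15 rose (0.0503 for higher). In embryos with OTX2 overexpression the MRPS genes had a median of 0.39 and 0.11 under median-ratio scaling, with 9 of 26 higher and 3 lower (0.586 for higher), and MRPL had 10 of 42 higher and 3 lower, beside lower RPL (26 of 47, 9.37e-16) and RPS genes (23 of 35, 6.79e-16). RBM genes were lower there in 8 of 29 (0.0282), with a median of 0.14.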
